A study of Citrus reticulata with 36 samples.

How the data were processed

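Gene expression was measured by RNA-seq in cells cut from ovules of ponkan mandarin (Citrus reticulata) by laser capture microdissection, in which a laser isolates chosen cells from a tissue section under the microscope. The nucellus, the maternal tissue that surrounds the embryo sac, and the integument, the outer layers that later form the seed coat, were captured at 18, 28 and 32 days after pollination (DAP). Each tissue and stage was taken from 2 cultivars, Huagan No. 4 ponkan, labelled MT, and Egan No. 1 ponkan, labelled WT. The labels do not spell out MT, and it is used here only as a name. The 12 groups of tissue, stage and cultivar hold 3 libraries each, 36 in all. Per the labels' protocols, a small amount of RNA from each capture was amplified with random primers and a linear amplification kit (SPIA) and sequenced as paired ends on 2 Illumina instrument models. The labels do not say which library ran on which model, so a difference between instruments cannot be told apart from other differences between libraries.

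The authors deposited a table of read counts and a table of FPKM (fragments scaled to feature length and to the library total) over the same 128861 features. The submitters' processing notes name cutadapt, Bowtie2, RSEM and DESeq, with no versions; the reference sequence they aligned to is not given in the sources used here. The labels' design text says that RNA of leaves and ovaries was pooled for long-read sequencing. RSEM gives estimated counts that need not be whole. Every value in the deposited count table was a whole number. The deposited values were taken to be RSEM expected counts that the authors had rounded, a step that none of the sources used here records, and were used as they stood. Within the 1765 features with over 500 counts in every library, the length implied by the deposited count and FPKM differed by a median factor of 1.041 and at most 1.291 between the highest and lowest library, and 25 values above 0 in the counts were listed at 0 in the FPKM table. RSEM splits reads between similar sequences, and a feature with a near-identical copy can therefore carry part of its copy's counts.

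The feature identifiers carry no gene names, and no reference was used here to supply them. The 18 gene lists fixed before the data were examined, which included markers of photosynthetic, vascular, endosperm and pollen tissue, could not be applied, and their tests are void. Features are named by identifier, and the naming rule took at most 2 that rose and 2 that fell in a comparison. The features called between cultivars at 18 DAP and the most abundant features are named outside that rule. The column names of both tables give tissue, cultivar and replicate as the labels do, but the stage as a digit from 1 to 3. These digits were read as 18, 28 and 32 DAP, in the order in which the design text lists the stages. Tissue differences over all libraries and the 6 cultivar differences as sets do not depend on this reading, but every DAP attached to a value does.

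Differences were tested with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr over the 12 groups, which left 57344, and these held 99.72% to 99.95% of the counts of each library. Libraries were scaled by TMM, with factors from 0.592 to 1.227, and 1 quasi-likelihood model with a mean for each of the 12 groups was fitted to all 36 libraries with robust dispersion estimates. The common biological coefficient of variation was 0.44. A feature was called at a Benjamini-Hochberg adjusted p under 0.05. The tissue contrast was the mean of the 6 nucellus-minus-integument differences within cultivar and stage, MT was compared with WT within each tissue and stage, and successive stages were compared within each tissue as the mean over both cultivars. Differences of differences were tested in the same model. The standard error of a log2 fold change was taken from the quasi-likelihood F statistic. Values per library are TMM-scaled CPM (counts scaled to a common library total), and log2 CPM was computed with a prior count of 2.

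The comparisons, the tests, the alternatives and the rule for naming features were fixed before the data were examined. That rule took called features with a mean log2 CPM at or above the median of the tested features. The libraries of both groups had to be fully separated, or, for means over several groups, the difference had to have the same sign in each. The features with the largest log2 fold changes were then named. The mean of the 6 cultivar differences was added after the data had been seen, and its features were named by the same rule.

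Total counts ran from 12687779 to 20947644 per library. On these unscaled totals 3 counts, taken as the most that a count of 0 allows, correspond to between 0.143 and 0.236 CPM, for counting error only. On the TMM-scaled CPM given for libraries, this level shifts with the TMM factor of each library and can lie outside that range. The reads carry no molecular identifiers, and amplified copies are not independent molecules. The labels call the 3 libraries of a group biological replicates without tying captures to plants. If captures of a group shared a plant, the p-values are too small. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom ran from 8.4 to 205.7 over the 36 pairs of libraries within groups.

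The main test was checked on simulated counts with 200 changed features among 57344. Each feature had an overall mean over all libraries, with the library sizes and feature dispersions of the real data. Changed features were drawn only from those at or above the median level. Counts were drawn independently, without tissue differences or variation shared between libraries, so the recovered shares can be too high for the real data. For the tissue contrast, 91% of the 2-fold and 98.5% of the 4-fold changes were recovered. For MT against WT in the integument at 32 DAP, the shares were 9% at 2-fold, 70.1% at 4-fold and 89.4% at 8-fold. For 28 against 18 DAP in the nucellus they were 34.3%, 88.1% and 97%. Between 4 and 11 unchanged features were called in these runs.

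The alternatives were RLE size factors, no filter on low counts, voom with sample quality weights and limma on log2(FPKM + 1) and log2(FPKM + 0.1) (limma 3.58.1), DESeq2 1.42.0, a model of the compared groups alone, a replicate block, and leaving out each library in turn. Added after the data had been seen were splits of the libraries that keep same-numbered captures together, 2 surrogate variables (sva 3.50.0), libraries thinned to 12687779 counts, and a covariate for a shared axis of variation between libraries.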

Results

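The transcriptomes of laser-captured nucellus and integument were profiled at 18, 28 and 32 DAP in the cultivars labelled MT and WT, as 36 libraries in 12 groups of 3. Each library held between 55947 and 69127 features above 0. Total counts ran from 12687779 (WT integument at 18 DAP, replicate 1) to 20947644 (WT integument at 28 DAP, replicate 1). Of the 128861 features in the tables, 34664 were at 0 in every library and 57344 were tested. The correlation of log2 CPM between libraries of a group had a median of 0.921 and ran from 0.806 to 0.975 over the 36 pairs of libraries, across features.

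Tissue was the main difference between the groups of libraries. The first principal component of log2 CPM held 28.3% of the variance, and tissue accounted for 97.2% of the spread along it. The second held 15.5%, with 1% of its spread accounted for by tissue and 43.9% by the 12 groups. Over all tested features, tissue accounted for 27.7% of the variance and the 12 groups for 54.7%, which left 45.3% between libraries of one group. Means of 12 groups of 3 libraries take up part of any variance even without a group effect. The shares of 43.9% and 54.7% were not corrected for this and cannot be read as effects of stage or cultivar. The 100 most abundant features took between 16.03% and 51.75% of a library's counts. The highest share was in the WT nucellus library of 28 DAP, replicate 1, which also had the lowest TMM factor, 0.592.

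**Figure D1:**
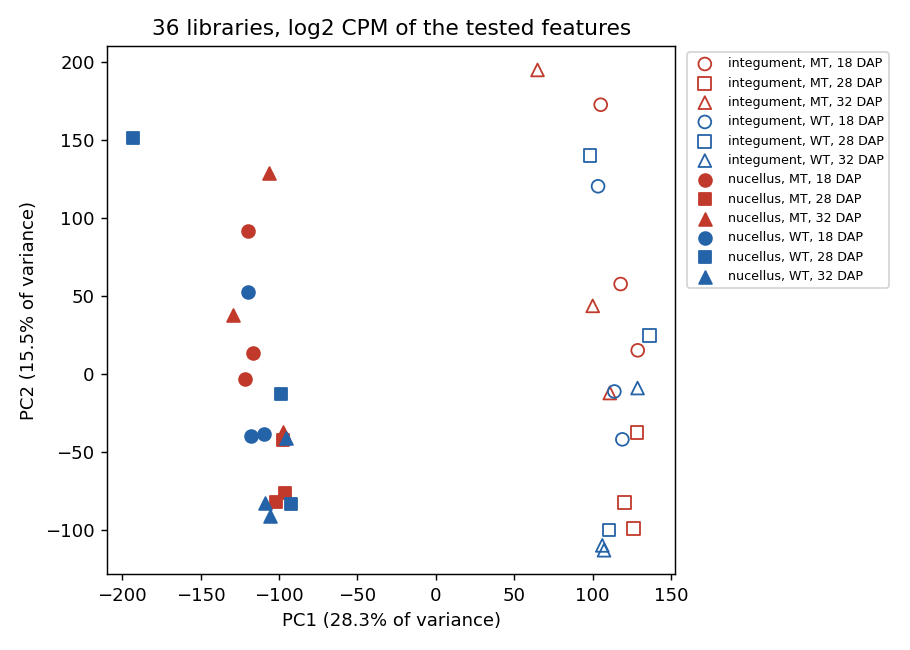
Scores of the 36 libraries on the first (28.3% of variance) and second (15.5%) principal components of log2 CPM over the 57344 tested features. Filled symbols are nucellus and open symbols integument, colour gives the cultivar and shape the stage, and the tissues separate along the first component.

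The comparison of nucellus with integument asked which transcripts distinguish the tissues of the ovule. In the nucellus, c36715_g1 averaged 588 ± 270 CPM (SD, n = 18) against 2.8 ± 1.94 CPM in the integument (n = 18), a log2 fold change of 7.71 ± 0.43 (SE; edgeR, adjusted p = 4.2e-14). The feature c95166_g1 averaged 879 ± 295 CPM in the nucellus and 5.05 ± 5.13 CPM in the integument, a log2 fold change of 7.64 ± 0.37 (edgeR, adjusted p = 2.3e-15). Its lowest nucellus library, at 272 CPM, lay above its highest integument library, at 23 CPM. In the opposite direction, c51494_g1 averaged 0.805 ± 0.461 CPM in the nucellus and 91.7 ± 35.1 CPM in the integument, a log2 fold change of -6.8 ± 0.22 (edgeR, adjusted p = 1.9e-19). The feature c97589_g1 averaged 0.647 ± 0.424 CPM in the nucellus and 63 ± 39 CPM in the integument, with a log2 fold change of -6.57 ± 0.5 (edgeR, adjusted p = 3e-11). Its integument values were uneven, from 1.1 to 139 CPM, and its lowest integument library lay below its highest nucellus library, at 1.62 CPM.

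**Figure D2:**
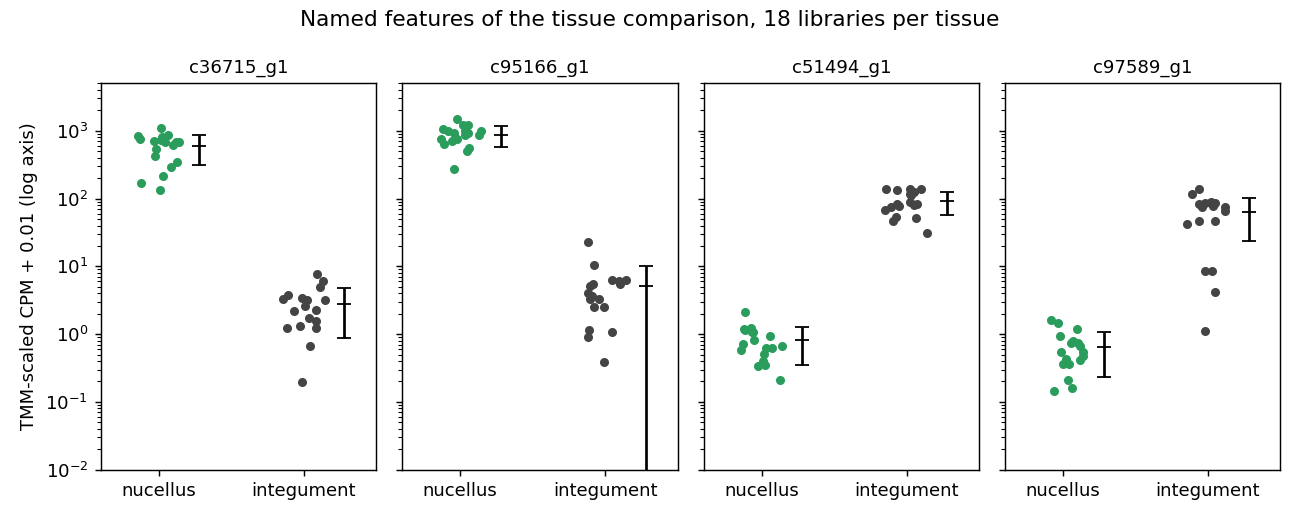
TMM-scaled CPM plus 0.01, on a log axis, of the 4 features named in the tissue comparison; each point is 1 library (18 per tissue) and the marks beside the points give the mean and SD. For c95166_g1 in the integument the SD is larger than the mean, so its lower arm runs off the axis. c36715_g1 averaged 588 CPM in the nucellus and 2.8 CPM in the integument, and c51494_g1 averaged 0.805 and 91.7 CPM.

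Over all tested features, 20358 (35.5%) differed between the tissues, 9500 higher in the nucellus and 10858 higher in the integument (edgeR, adjusted p under 0.05). On FPKM the counts of higher calls were nearly even, 10239 in the nucellus and 10132 in the integument on log2(FPKM + 1) and 9914 and 9905 on log2(FPKM + 0.1). Large differences were mostly on the integument side: 3218 features were over 4-fold higher there and 1162 in the nucellus, and 954 against 330 were over 16-fold higher. Of the called features, 80.5% had the same sign in each of the 6 combinations of cultivar and stage. Every nucellus library lay above every integument library for 353 of the tested features, and the reverse held for 861. Nucellus-high features took 24.8 ± 3.4% of the counts of nucellus libraries (SD, n = 18) and 13.8 ± 1.1% of those of integument libraries. Integument-high features took 37.4 ± 3.7% in the integument and 21.6 ± 3.3% in the nucellus. These 4 shares were measured on features called in the same libraries. The labels do not say whether captures of both tissues came from the same ovules.

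The cultivar comparison asked how MT differed from WT within each tissue and stage. In the integument at 32 DAP, c40866_g1 averaged 55.9 ± 45.1 CPM in MT (SD, n = 3) and 0.195 ± 0.131 CPM in WT (n = 3), a log2 fold change of 8.12 ± 1.47 (SE; edgeR, adjusted p = 0.012). The WT level rests on 12 counts over the 3 libraries, so the size of this fold is poorly set. The feature c109595_g1 averaged 339 ± 253 CPM in MT and 1.88 ± 2.47 CPM in WT, a log2 fold change of 7.5 ± 1.77 (edgeR, adjusted p = 0.037). Lower in MT were c74588_g1, with a log2 fold change of -5.07 ± 1.24 (edgeR, adjusted p = 0.044; the call was lost in 25 of 47 settings), and c128315_g1, with -3.04 ± 0.61 (edgeR, adjusted p = 0.016). The WT libraries of c74588_g1 spread from 4.24 to 167 CPM, the lowest of them next to the highest MT library, at 4.13 CPM. In the other groups these features also varied between libraries: c40866_g1 ran from 0 to 81.9 CPM and c109595_g1 from 0.0993 to 501 CPM.

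In that comparison 583 features were called, 512 higher and 71 lower in MT. On log2(FPKM + 1) the higher and lower calls were 758 and 390, and with voom 2792 and 905. The count rested on single libraries. It was 0 without WT replicate 2, 3 without WT replicate 3 and 6 without MT replicate 2, but 1401 without MT replicate 1. Leaving out a library of another group, WT integument at 28 DAP, gave 1042 for replicate 1 and 932 for replicate 2. It was also 0 when only these 6 libraries were modelled. WT replicates 2 and 3 of this group were the closest of the 36 pairs of libraries within groups. Their chi-square per degree of freedom was 8.4 and their r of log2 CPM 0.975. The WT nucellus libraries of the same numbers and stage came next, with 10.7 and 0.971. If captures of such a pair shared a plant, the p-values are too small.

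In the nucellus at 32 DAP, c57814_g1 averaged 44.9 ± 33.9 CPM in MT and 2.06 ± 0.542 CPM in WT (SD, n = 3 each), a log2 fold change of 4.45 ± 0.78 (edgeR, adjusted p = 0.026). For c5775_g1 the means were 26.4 ± 14.1 and 1.97 ± 1.96 CPM, a log2 fold change of 3.73 ± 0.74 (edgeR, adjusted p = 0.047). The only feature that met the naming rule among those lower in MT, c15909_g1, averaged 43.3 ± 9.05 CPM in MT and 133 ± 47.4 CPM in WT, a log2 fold change of -1.62 ± 0.32 (edgeR, adjusted p = 0.045). The calls of c5775_g1 and c15909_g1 were lost in 28 and 25 of 47 settings. In all, 31 features were called, 29 higher and 2 lower in MT, against 782 and 296 with voom and 363 and 79 with DESeq2. Without 1 MT library the count was 276 (replicate 1), 0 (replicate 2) and 0 (replicate 3), and without 1 WT library it was 5, 0 and 1. It rose to 146 without WT nucellus at 28 DAP, replicate 1, and to 51 without WT integument at 28 DAP, replicate 1, and lay between 13 and 18 without each of 18 other libraries. It was 0 with these 6 libraries modelled alone.

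At 18 DAP, 1 feature was called in the nucellus and 4 in the integument, all lower in MT and named here although the naming rule took none of them, so they were chosen after their values were seen. In the nucellus c6063_g1 had a log2 fold change of -2.52 (edgeR, adjusted p = 0.028). In the integument c1342_g1 had -7.6, c63760_g1 -5.09, c64041_g1 -3.05 and c7758_g1 -3.06 (edgeR, adjusted p from 0.0153 to 0.0414). The nucellus call was lost without MT replicate 2 or 3 or WT replicate 1 or 3 of its group, and without WT integument replicate 2 of 18 or of 32 DAP. The integument count was 0 without MT replicate 2 or 3 or WT replicate 1 or 2 of its group, and 16 without WT nucellus at 28 DAP, replicate 1. Both counts were 0 when only the compared libraries were modelled. The direction was not one-sided under every setting: higher and lower calls in the nucellus were 12 and 4 on log2(FPKM + 1), 8 and 8 with DESeq2 and 1 and 0 with voom, and in the integument 28 and 87 with DESeq2, 7 and 19 with voom and 17 and 21 with surrogate variables.

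At 28 DAP no feature was called between MT and WT in either tissue (edgeR). In the nucellus 7085 features had an unadjusted p under 0.05; DESeq2 called 544, voom with quality weights 207, and limma 24 on log2(FPKM + 1) and 13 on log2(FPKM + 0.1). The edgeR count became 497 without WT replicate 2, 246 without WT replicate 3 and 26 without MT replicate 1. It stayed at 0 without each other library, WT replicate 1 among them. That library had the lowest voom quality weight, 0.132, and stayed in the fits that gave 497 and 246. In the integument 3841 had an unadjusted p under 0.05; DESeq2 called 32, voom 290 and limma 0 on both FPKM scales.

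**Figure D3:**
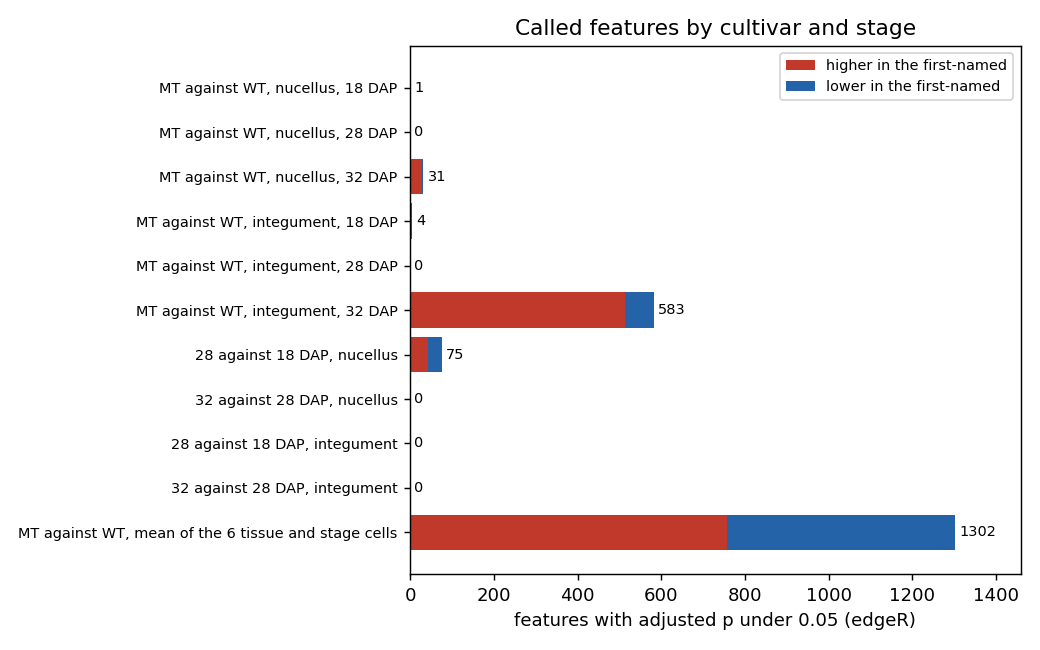
Number of features with an edgeR adjusted p under 0.05 in each comparison of cultivars or stages, out of 57344 tested; red counts features higher and blue features lower in the first-named group. MT against WT over all 6 tissue and stage cells gave 1302 and the integument at 32 DAP gave 583.

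No feature was called between MT and WT in the same direction in all 6 tissue and stage cells (edgeR). This count was 0 by construction, because none was called at 28 DAP in either tissue. In the simulated counts only 9% of 2-fold changes were recovered in the integument at 32 DAP. A call in all 6 cells therefore says little about a small shared difference. At an unadjusted p under 0.05, 0 features had the same sign in all 6 (edgeR). DESeq2, voom and limma also called 0 after adjustment; at an unadjusted p under 0.05 with the same sign in all 6, DESeq2 had 0, voom 1, and limma 1 on log2(FPKM + 1) and 2 on log2(FPKM + 0.1). The mean of the 6 cultivar differences, a contrast added after the data had been seen, uses all 18 libraries of each cultivar. Same-numbered nucellus and integument libraries enter it as independent, though their deviations from the group means correlated with a median r of 0.275. If they are pairs, the standard errors and p-values of this contrast are too small. The feature c54395_g1 averaged 13.9 ± 10.6 CPM in MT and 5.55 ± 4.15 CPM in WT (SD, n = 18 each), a log2 fold change of 1.39 ± 0.27 (edgeR, adjusted p = 0.012). For c48157_g1 the log2 fold change was 1.44 ± 0.39 (edgeR, adjusted p = 0.049), with values from 0.275 to 102 CPM in MT and from 0.118 to 57.5 CPM in WT. This call was lost in 35 of 47 other settings, 30 of which left out 1 library (edgeR, adjusted p up to 0.105). Lower in MT were c9391_g1, with a log2 fold change of -1.15 ± 0.24 (edgeR, adjusted p = 0.016), and c1999_g1, with -1.05 ± 0.19 (edgeR, adjusted p = 0.0068). These 4 features differed in the stated direction in each of the 6 cells, which the naming rule required.

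By this contrast 1302 features differed, 757 higher and 545 lower in MT, with a median absolute log2 fold change of 0.62. The excess of higher calls depended on the setting: higher and lower calls were 614 and 585 with RLE, 1503 and 1489 with DESeq2, and 669 and 288 on log2(FPKM + 1). When the cultivar labels were reassigned with same-numbered captures of both tissues kept together, 3 of 25 splits, the real one included, called as many, the highest other 1824. The sign was the same in all 6 cells for 680 of the 1302 features (52.2%), although the features were chosen by the mean of those 6 differences. For 0 features did every MT library lie above every WT library, or the reverse. The count was 2206 without WT nucellus at 28 DAP, replicate 1, and 2020 without WT integument at 28 DAP, replicate 1. It fell to between 552 and 836 without each of 12 other libraries, named with their values beside the other effects of processing.

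Whether the cultivar difference itself differed between tissues was tested as a difference of differences. No feature was called between nucellus and integument (edgeR; 1641 at an unadjusted p under 0.05; DESeq2 gave 2, voom and limma 0). A change of the cultivar difference over the stages was called for 217 features in the integument and 0 in the nucellus (edgeR; 6634 at an unadjusted p under 0.05 in the nucellus, where DESeq2 gave 399, voom 186 and limma 1 and 0). The integument count was 0 without WT replicate 2 or WT replicate 3 of 32 DAP, 10 without MT replicate 2, 431 without MT replicate 1 and 473 without WT replicate 1 of that stage. Those WT replicates 2 and 3 were the closest pair of libraries within groups, with an r of log2 CPM of 0.975. Without a 28 DAP integument library the integument count was 127, 14 and 21 for MT replicates 1, 2 and 3, and 27 and 1075 for WT replicates 1 and 2. It was 0 with the integument modelled alone.

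The stage comparison asked what changed as the ovule developed. In the nucellus from 18 to 28 DAP, c11808_g1 fell from 78.7 ± 21 to 13.4 ± 5.59 CPM (SD, n = 6 each), a log2 fold change of -2.62 ± 0.54 (edgeR, adjusted p = 0.04). The feature c44063_g1 fell from 3.1 ± 1.91 to 0.592 ± 0.442 CPM, a log2 fold change of -2.5 ± 0.48 (edgeR, adjusted p = 0.025). The feature c98051_g1 rose from 2.27 ± 0.68 to 12.3 ± 14.5 CPM, a log2 fold change of 2.24 ± 0.38 (edgeR, adjusted p = 0.015), and c17763_g1 rose from 5.34 ± 1.89 to 20.7 ± 26.2 CPM, with 1.8 ± 0.38 (edgeR, adjusted p = 0.041). Both means at 28 DAP were raised by WT replicate 1, the library with the highest share of counts in 100 features, which held 41.9 CPM of c98051_g1 and 73.8 CPM of c17763_g1.

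In all, 75 features changed in the nucellus from 18 to 28 DAP, 42 higher and 33 lower at 28 DAP. The balance turned under other settings, with higher and lower calls of 6 and 116 on log2(FPKM + 1), 12 and 64 on log2(FPKM + 0.1), 757 and 1143 with voom and 412 and 492 with surrogate variables, but 550 and 359 with DESeq2. The calls of c17763_g1 and c11808_g1 were lost in 22 and 16 of 47 settings. Of the 75 features, 97.3% had the same sign in the integument and 23 also had an unadjusted p under 0.05 there. Among all 57344 tested features, 5491 had an unadjusted p under 0.05 there. Same-numbered libraries of both tissues shared deviations from their group means, at a median r of 0.275, so the integument is not independent support. Without a 28 DAP library the nucellus count was 726, 5 and 10 for MT replicates 1, 2 and 3, and 236, 161 and 360 for WT replicates 1, 2 and 3. Without an 18 DAP library it was 17 and 8 for MT replicates 2 and 3, and 14, 48 and 20 for WT replicates 1, 2 and 3, and 2 with the 4 compared groups modelled alone.

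No feature was called from 28 to 32 DAP in the nucellus (edgeR; 5259 at an unadjusted p under 0.05; DESeq2 gave 42, voom 8 and limma 0), where leaving out WT 28 DAP replicate 1 gave 1. In the integument no feature was called from 18 to 28 DAP (5491 at an unadjusted p under 0.05; DESeq2 gave 181, voom 1233 and limma 145 and 61). That count was 290 without WT 28 DAP replicate 1, 6 without WT 18 DAP replicate 2, and 2 without MT 32 DAP replicate 2 or replicate 3. From 28 to 32 DAP in the integument none was called (2823 at an unadjusted p under 0.05; DESeq2 gave 63, voom 19 and limma 2 and 0), with 9 without MT 32 DAP replicate 3. Leaving out WT 28 DAP or WT 18 DAP integument replicate 1, or nucellus MT 18 DAP replicate 3, WT 28 DAP replicate 1 or WT 28 DAP replicate 3, gave 1.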

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

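The test of whether the cultivar difference changed over the stages was planned, and the surrogate variables and the axis covariate quoted with it were added after the result was seen. In the integument the difference between MT and WT itself differed between stages for 217 features. The libraries were split 25 ways, the real one and 24 with MT and WT labels reassigned within each tissue and stage. Only the real split gave as many calls, and the highest other split gave 0. The share of 0.04 is the smallest that 25 splits allow. It is not adjusted over the 16 comparisons with a count, so it does not by itself exclude chance. The count was 24 with the axis covariate and 9 with surrogate variables, and it ran from 0 to 1075 when single libraries were left out.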

How the results depend on the processing

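The surrogate variables, the thinned libraries, the axis covariate and all values of the mean over the 6 tissue and stage cells were chosen after the data had been seen; the other settings were planned. The tissue count stayed within 1.5 times of 20358 in all 46 settings that changed the fit, from 18759 with no low-count filter to 24423 with voom, and from 19207 to 21299 without single libraries. Without 1 library at least 19034 of the 20358 features kept their call and 0 changed sign. The named tissue features kept sign and call in all 47 settings, of which the model of compared groups alone is the same fit for them. Over the 19 features named by the rule, 0 changed sign in 893 combinations of feature and setting. The call was kept in 710 combinations and lost in 183, most often for c48157_g1 (35 of 47), c5775_g1 (28), c15909_g1 (25) and c74588_g1 (25). Features named outside the rule were not followed in this way. Counts of cultivar and stage calls moved far more, and the cause was not tested unless stated. In the simulated counts, 9% of 2-fold and 89.4% of 8-fold changes were recovered in the integument at 32 DAP, with 3 libraries against 3. These were features at or above the median level, without variation shared between libraries.

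With voom and sample quality weights the counts for MT against WT were 207 and 1078 in the nucellus at 28 and 32 DAP and 26, 290 and 3697 in the integument at 18, 28 and 32 DAP. Voom gave 1900 for 28 against 18 DAP and 8 for 32 against 28 DAP in the nucellus, 1233 and 19 in the integument, 186 and 4372 for the change of the cultivar difference over stages in nucellus and integument, and 4663 for the mean over the 6 cells. DESeq2 gave 16, 544 and 442 in the nucellus and 115, 32 and 1919 in the integument at 18, 28 and 32 DAP. For the stages it gave 909 and 42 in the nucellus and 181 and 63 in the integument, for the differences of differences 2 between tissues and 399 and 1259 over stages in nucellus and integument, and 2992 for the mean over the cells. Neither tool reversed a feature called in both: voom shared 573 and DESeq2 578 of the 583 features of the integument at 32 DAP.

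On log2(FPKM + 1) limma gave 16, 24 and 88 for MT against WT in the nucellus at 18, 28 and 32 DAP, 7 and 1148 in the integument at 18 and 32 DAP, 122 for 28 against 18 DAP in the nucellus, 145 and 2 for the stage steps in the integument, and 1 and 142 for the change over stages in nucellus and integument. On log2(FPKM + 0.1) it gave 5 and 13 in the nucellus at 18 and 28 DAP, 14 in the integument at 18 DAP, 61 for 28 against 18 DAP in the integument and 142 for the change over stages there. FPKM are scaled by total counts, which moves the median of all features by up to 0.27 (log2) against TMM, for MT against WT in the nucellus at 28 DAP, while RLE moves it by at most 0.03. The split into higher and lower calls moved with FPKM: 758 and 390 (pseudocount 1) or 590 and 203 (0.1) for MT against WT in the integument at 32 DAP against 512 and 71, 6 and 116 or 12 and 64 for 28 against 18 DAP in the nucellus against 42 and 33, and 669 and 288 or 610 and 276 for the mean over the cells against 757 and 545.

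With no low-count filter, which tests more features, the counts were 0 for MT against WT at 18 DAP in nucellus and in integument, 328 in the integument at 32 DAP, 1 for 28 against 18 DAP in the integument, 1 and 102 for the change over stages in nucellus and integument, and 734 for the mean over the cells. RLE gave 1 for 32 against 28 DAP in the integument. With only the compared libraries modelled, which leaves fewer libraries to estimate the spread, the counts were 0 for MT against WT at 18 and 32 DAP in both tissues, 2 for 28 against 18 DAP in the nucellus and 0 for the change over stages in the integument. Surrogate variables gave 60 in the nucellus at 32 DAP, 38 and 302 in the integument at 18 and 32 DAP, 904 for 28 against 18 DAP in the nucellus, 32 and 1 for the stage steps in the integument, 9 for the change over stages there and 3895 for the mean. Thinned libraries gave 0 in the nucellus and 2 in the integument at 18 DAP. The axis covariate gave 0, 1 and 3 in the nucellus at 18, 28 and 32 DAP, 145 in the integument at 32 DAP, 751 for 28 against 18 DAP in the nucellus and 19 in the integument, 24 for the change over stages in the integument and 2798 for the mean.

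Without single libraries the counts for MT against WT ran from 0 to 1, 0 to 497 and 0 to 276 in the nucellus at 18, 28 and 32 DAP, and from 0 to 16, 0 to 0 and 0 to 1401 in the integument. They ran from 5 to 726 and 0 to 1 for the stage steps in the nucellus and from 0 to 290 and 0 to 9 in the integument. The change over stages gave 0 to 20 in the nucellus, with 20 and 10 without WT 28 DAP replicates 2 and 3, 1 without MT 18 DAP replicate 2 or 3 and 4 without MT 32 DAP replicate 1, and 0 to 1075 in the integument. The difference between tissues and the features shared by all 6 cells gave 0 throughout. For all 6 cells no other count was possible, because the integument at 28 DAP stayed at 0. For the mean over the cells the range was 552 to 2206. It was 740 without nucellus WT 18 DAP replicate 3, 836 without MT 28 DAP replicate 1, 729 without MT 32 DAP replicate 3, and 603 and 594 without WT 32 DAP replicates 2 and 3. For the integument it was 810 without MT 18 DAP replicate 3, 805 without WT 18 DAP replicate 2, 552 without MT 28 DAP replicate 1, 659 and 740 without WT 28 DAP replicates 2 and 3, and 697 and 635 without WT 32 DAP replicates 2 and 3.

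The replicate numbers were not taken to pair nucellus and integument libraries, because the correlation of their deviations from the group means was over 0.1 in 17 of the 18 same-numbered pairs and not in all. It ran from 0.05 to 0.48 with a median of 0.275, and 17 of 18 nucellus libraries correlated best with the integument library of their own number. Between MT and WT libraries of the same tissue and stage, 6 of 18 correlated best with their own number, with a median of 0.04. The data thus point to pairing of the tissues, though the labels do not state it. For the tissue contrast and the difference between tissues the replicate block was each same-numbered pair, and 24397 features were called between the tissues. For all other comparisons it was the replicate number alone, shared by the 12 groups, which does not model such pairs. There it gave 510 for MT against WT in the integument at 32 DAP and 173 for the change over stages. No count moved by over 1.5 times, which for cultivar and stage counts does not test pairing. Of the named features, the replicate number as a block ended the calls of c11808_g1 (edgeR, adjusted p = 0.0531) and c48157_g1 (edgeR, adjusted p = 0.0615). Summing isoforms gave no value, because every identifier carried the same suffix, and camera on the gene lists gave none, because the features have no gene names.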

Other observations

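The tests of shared material, of complexity, of the median leading feature and of predicted signs at 32 DAP, every test by thinning or by the axis covariate, the mean over the 6 cells and the splits that keep same-numbered captures together were chosen after the results were seen; the other splits of libraries were planned. The most abundant feature of the tables, c94721_g1, took 5.53 ± 1.63% of the counts of nucellus libraries and 8.01 ± 1.63% of those of integument libraries (SD, n = 18 each), a log2 fold change of -0.59 (edgeR, adjusted p = 0.0011). The feature c65670_g1 took 1.31 ± 0.37% and 2.53 ± 0.71%, a log2 fold change of -0.98 (edgeR, adjusted p = 1.3e-07), and c122222_g1 took 1.39 ± 1.31% and 1.15 ± 0.81%, with 0.26 (edgeR, adjusted p = 0.67). These features were picked for their abundance after the values were seen.

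Across the tested features, which are not independent replicates, the log2 fold changes from 18 to 28 DAP correlated between nucellus and integument with r = 0.33, and those from 28 to 32 DAP with r = 0.35. The MT against WT fold changes correlated between the tissues with r = 0.29, 0.25 and 0.38 at 18, 28 and 32 DAP. Within the integument r was 0 for 18 with 28 DAP, 0.16 for 18 with 32 DAP and -0.33 for 28 with 32 DAP, and within the nucellus 0.04, 0.11 and -0.17. Of the 583 features called in the integument at 32 DAP, 89% had the same sign in the nucellus at 32 DAP, 77.4% in the integument at 18 DAP and 13.7% in the integument at 28 DAP. Libraries also differed along an axis within groups, described below. Opposite signs at 28 and 32 DAP thus do not by themselves show a reversed cultivar difference. Same-numbered libraries of the tissues already share deviations from their group means at a median r of 0.275, so the correlations between tissues do not by themselves show shared stage or cultivar effects. The labels do not say whether captures of both tissues came from the same ovules.

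The WT nucellus library of 28 DAP, replicate 1, stood apart on several measures. At equal depth it held 53654 features above 0, against 57208 in the next lowest library and 66855 in the highest. Of 18205 features at 5 to 20 CPM in the other nucellus libraries, 2.03% were at 0 in it after thinning, against 0.137% in the next library. Its voom quality weight was 0.132, and its features of high integument level averaged -2.65 log2 CPM, below the median of -2.24 in the other nucellus libraries. Its features of high nucellus level averaged 1.15 log2 CPM, the lowest of the 18 nucellus libraries, where the next was 1.37 and the highest 2.28.

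Within groups, libraries of both tissues differed along a shared axis. The axis, taken from the deviations of integument libraries from their group means, held 31.9% of their within-group variance, and the 200 features leading its high end ranged over a median of 7.06 (log2 CPM) across integument libraries. Scores of nucellus libraries on it, 6.7% of their within-group variance, followed those of the same-numbered integument libraries with r = 0.98 and Spearman rho = 0.98 over 18 pairs (exact permutation within groups, p = 0.00026 and p = 0.00013, two-sided, 46656 arrangements), with r = 0.97 without the 2 farthest pairs. Of the 200 features leading the high end, 79% had their highest integument value over 1 (log2 CPM) above every nucellus library, as did 34% of the 200 leading the low end, and across features, which are not independent replicates, the weight on the axis had a Spearman rho of 0.09 with the implied length.

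Technical measures were set against the score in 4 relations over 18 group-centred libraries each, with exact two-sided permutation within groups and adjusted p over the 4. With log2 total counts, r in the integument was 0.2 (95% interval -0.39 to 0.68, p = 0.59, adjusted 0.59; Spearman rho = 0.14, p = 0.67, adjusted 0.67; r = 0.27 without the 2 farthest libraries). In the nucellus it was 0.32 (-0.28 to 0.74, p = 0.41, adjusted 0.59; rho = 0.36, p = 0.26, adjusted 0.51; 0.22 without the 2 farthest). With the number of features at equal depth, r was -0.21 in the integument (-0.68 to 0.38, p = 0.53, adjusted 0.59; rho = -0.18, p = 0.57, adjusted 0.67; -0.4 without the 2 farthest). In the nucellus it was -0.51 (-0.83 to 0.06, p = 0.094, adjusted 0.38; rho = -0.43, p = 0.11, adjusted 0.44; -0.44 without the 2 farthest).

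Sequencing depth is argued against by thinning, a test taken up because the correlation with depth had been seen not to decide: at one depth the axis still held 31.9% of the variance, with scores at r = 1 to the unthinned ones. Carry-over of integument RNA into nucellus captures is argued against only for the summed change, which a few of the 168 to 200 leading features used per group can carry: relative to the integument it was over 3 times the ratio of levels of integument-high features in 5 of 6 cultivar and stage groups. For the median leading feature it cannot be told apart, with a change above that ratio in 3 of 6 groups but far below it in MT at 18 DAP (0.17% against 1.77%), WT at 18 DAP (0.597% against 1.79%) and WT at 28 DAP (0.263% against 1.39%). Library complexity cannot be told apart either, since the interval around r = -0.21 takes in both no relation and a strong one. A candidate explanation is that same-numbered captures shared plant material, which r = 0.98 is consistent with but the labels do not state.

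The 583 features called between MT and WT in the integument at 32 DAP may largely follow the same axis. An axis was built from the 18 and 28 DAP integument libraries, and its direction was set by the MT minus WT score difference of the 32 DAP libraries themselves. It gave the sign of 96.7% of the 583 (exact binomial 95% interval 95 to 98, features taken as independent, which they are not). For all tested features the share was 67.2%. Because the direction came from the same libraries, some agreement was built into both shares. With the axis score as a covariate 145 were called, 135 of them among the 583, and the median absolute log2 fold change of the 583 went from 2.96 to 1.82, so the axis and a cultivar difference cannot be told apart for the rest. A difference in depth is argued against, since 531 were called after thinning. A cultivar difference at this stage stays open, and the mean axis scores of 60.4 ± 125.3 in MT and -77.5 ± 62.4 in WT (SD, n = 3 each) overlap in spread. The scores of replicates 1, 2 and 3 were -24.7, 204.3 and 1.7 in MT and -5.4, -112.8 and -114.2 in WT, so the MT mean rested on replicate 2. In the integument at 28 DAP the scores were -53.7, -85.7 and -71.3 in MT and 158.7, -111.8 and 22.6 in WT. The highest there was WT replicate 1.

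The 1302 features of the mean over the 6 cells were not accounted for by position on the axis. With the axis score as a covariate 2798 were called, 1270 of them among the 1302, and after thinning 1081 were called, 994 among the 1302, which argues against axis position and depth as the whole cause. Chance assignment of the cultivar labels is not excluded, because 3 of 25 splits that kept same-numbered captures together called as many. A cultivar difference present in both tissues may remain only as 1 of the open explanations. Sequence differences between the cultivars and the reference used for counting, which could shift counts in the same way, were not tested.

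Counts of calls were set against other splits of the same libraries, 10 for each tissue and stage and 25 elsewhere, the real one included. For the tissue comparison 1 of 25 splits gave as many calls, the real one with 20358, and the highest other gave 1. This argues against chance, but the share of 0.04 is the smallest that 25 splits allow. It is not adjusted over the 16 comparisons with a count, so it does not by itself exclude chance. Splits that mix nucellus and integument within groups also put the tissue difference into the spread, which leaves them few calls. For the mean over the cells 1 of 25 splits gave as many, with 1302 against 0, when labels were reassigned separately in each tissue. Deviations of same-numbered captures from their group means correlated over 0.1 in 17 of 18 pairs, which misses the rule set for pairing, but splits that part them can understate the spread of the mean. With the pairs kept, 3 of 25 gave as many, with 1824 in the highest other and 0 in 19, so chance cannot be excluded for this count. For 28 against 18 DAP in the nucellus 2 of 25 gave as many, with 75 against 511 in the highest other, so the share of splits does not exclude chance. That other split parts the libraries as the stages do except for WT replicate 2 of 18 DAP and WT replicate 1 of 28 DAP, so it largely restates the real labels, and the remaining 23 gave 0. For MT against WT within 1 tissue and stage there are only 10 splits, too few for a share under 0.1. The real and the highest other counts were 1 and 0, 0 and 111, and 31 and 0 in the nucellus at 18, 28 and 32 DAP, and 4 and 0, 0 and 0, and 583 and 1 in the integument. In the other comparisons with a real count of 0, all 25 splits reach that count by construction, so the splits test nothing. The highest other counts there were 0 for 32 against 28 DAP in the nucellus, 23 and 1511 for 28 against 18 and 32 against 28 DAP in the integument, 97 for the difference between tissues, 1 for the change over stages in the nucellus and 0 for all 6 cells.

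Some splits called features where the real labels called 0. The 1511 for 32 against 28 DAP in the integument, the 97 for the difference between tissues and the 1824 for the mean over the cells point to a structure of the libraries other than the labels compared. In the split with 1511, libraries labelled 28 DAP scored from -114.2 to -24.7 on the within-group axis and those labelled 32 DAP from -71.3 to 204.3. Another split of that comparison, which exchanged the labels of all WT libraries of both stages, gave 807. It keeps the 12 groups whole and sets the stage changes of the cultivars against each other, so it is not a chance split. The 111 in the nucellus at 28 DAP came from a split that parts the libraries as the cultivar labels do except for replicate 1 of each cultivar.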
